A study of Mus musculus with 8 samples.

How the data were processed

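Per the file headers, the deposited tables hold 1 FPKM value per library (fragments per kilobase of transcript per 1e6 mapped fragments), with the authors' p-value, the authors' fold as a ratio between groups and the deposited signal, which is the group mean of counts that the authors normalized. Each of 4 tables compares 2 groups. The submitters' processing notes name CASAVA 1.8.2, FastQC 0.11.5, Trim Galore 0.4.1, HISAT2 2.0.5, HTSeq 0.6.1p1, DESeq2 1.10.1 and DESeq, with mm10 as the genome, and the deposited annotation columns name Ensembl build 87. The notes do not give the role of each tool, so the model behind the authors' p-values was not known. Libraries were made per the labels from total RNA with a stranded mRNA kit. Symbols and coordinates came from GENCODE vM21, matched by Ensembl identifier.

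The tables held 26804 genes, of which 22977 had FPKM in all 8 libraries. Left out were 26 genes whose FPKM differed between tables and 5 with a failed or low-data status, leaving 22946. Of 27 genes with values that depended on the table, 22 encode selenoproteins. Genes of biotypes other than protein coding held 36.7% to 56.6% of the FPKM of a library, and 3827 genes lacked a value in some library. Genes were tested if they had at least 1 FPKM in at least 2 libraries, which left 12729.

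FPKM sums differed between libraries, so FPKM was scaled by an unweighted trimmed mean of log ratios (trim 0.3 of the ratios and 0.05 of the levels), with factors from 0.487 to 1.58. The scaled values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 in a single model of 4 groups, with empirical Bayes variances that followed the expression level. P-values were adjusted by Benjamini-Hochberg within each comparison at 0.05. The plan had assumed counts for each library. Because the tables gave FPKM for each library, limma on logged values was used, and scaling between libraries was added after the values were seen. The edgeR and DESeq2 tests and limma-voom need counts per library and were not run. The median of the log2 change here minus that of the deposited fold was 0.011 for MoMF, -0.024 for KC, 0.068 for treated and 0.023 for untreated MoMF against KC.

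Depth was estimated from the deposited group means. Genes with FPKM in 1 library of a group only have group means that are multiples of a step, and between 81.6% and 97.8% of these values lay within 0.05 of a whole multiple. The step gave between about 5.95 and 19.7 M counts per library. Treated libraries came out higher in the comparison of treated MoMF with treated KC, the only one to list the mitochondrial rRNA genes mt-Rnr1 and mt-Rnr2.

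Gene lists of pathways, macrophage states and other cell types were written before the data were examined, 31 lists in all. Each was tested in each comparison with camera at a fixed correlation of 0.01, adjusted over all 155 tests, and again with the correlation estimated for each list, and with fry. Members were also adjusted over the list alone. Genes were named by rule. These were 12 genes per comparison with the largest called changes in both directions among genes in the top quartile of expression in the higher group (at least 18.0, 16.7, 17.3, 18.1 and 21.2 FPKM for MoMF, KC, treated, untreated and the interaction), a fixed set of marker genes, and the members of each called list with the smallest p or going against it.

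In a self-test, 100 genes per size were given a known change in values drawn with the mean and spread of each gene, after which libraries were multiplied by made-up factors. Of 4-fold changes, 82% were recovered in MoMF, 78% in KC, 80% and 83% between treated and between untreated populations and 69% in the interaction. Recovery of 2-fold changes was 33%, 25%, 36%, 39% and 5%. False calls numbered 4, 10, 5, 5 and 5 among 11927, 11919, 11934, 11916 and 11914 genes. The made values varied independently from gene to gene around 1 mean for all groups. Few genes were changed, as many up as down. The measured genes are correlated and many more were called, so recovery and false calls may differ there. A changed list was called in all 5 comparisons, and 1 unchanged list was called in the untreated one.

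The alternatives were median-ratio scaling, no filter on expression, a filter at 5 FPKM, pseudocounts of 0.1 and 5, only the 4 libraries of the groups compared, a replicate block and each library left out in turn. Added after the data were seen were no scaling, the authors' deposited p-values adjusted by Benjamini-Hochberg, and subtraction of a Kupffer cell share from treated MoMF. That share was the median ratio to treated KC over 14 Kupffer cell genes with under 5% of the untreated KC level in untreated MoMF. Tools were R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.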

Results

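RNA was read from hepatic macrophages that had been sorted by flow cytometry from livers of C57BL6/J mice. The labels name 2 populations. KC are Kupffer cells, the resident macrophages of the liver sinusoids, and MoMF were taken to be monocyte-derived macrophages, which arise from blood monocytes. Each population carried the label treated or untreated, giving 4 groups of 2 libraries. The only treatment described in the labels was a diet lacking methionine and choline, given for 4 weeks from 8 weeks of age, which causes fat storage and inflammation in mouse liver. The extraction text describes this diet for every sample, so what set treated apart from untreated was not settled, and both words are used only as labels. The labels do not say that the libraries of a group came from separate mice, so the p-values measure only the spread between these samples, which may be technical.

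Between 9470 genes (untreated KC library 1) and 12311 genes (treated MoMF library 1) reached 1 FPKM. The estimated depth was lower in the untreated than in the treated libraries. It was about 5.95 M counts in untreated KC library 1. For treated MoMF library 1 it was about 18.0 M counts against untreated MoMF and 19.7 M against treated KC, a comparison that lists more genes. FPKM sums ranged from 265475 to 898307, so all libraries were scaled to a common trimmed mean before testing. The libraries of a group had Pearson correlations of 0.968 (treated MoMF), 0.953 (untreated MoMF), 0.968 (treated KC) and 0.934 (untreated KC). The first principal component held 46.7% of the variance and the second 25.3%. Changes are given on the scale of log2(scaled FPKM + 1) with SE and n = 2 libraries per group. This scale understates the changes of genes of low expression. Folds are taken from it, so they can be far smaller than the ratio of the FPKM values printed beside them.

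Treated MoMF held more RNA of genes of lipid-laden and phagocytic macrophages than untreated MoMF, and less RNA of monocyte genes. Gpnmb, a glycoprotein of lysosomal membranes in lipid-laden macrophages, rose from 1.52 ± 0.667 FPKM (SD, n = 2) in untreated to 172 ± 28.2 FPKM (SD, n = 2) in treated MoMF, a 69.7-fold rise (log2 change 6.12 ± 0.24, SE; adjusted p = 9.11e-05). Spp1, which encodes the secreted matrix protein osteopontin, rose 25.2-fold from 1.68 ± 0.922 to 64.7 ± 6.39 FPKM. Ly6c2, a surface marker of inflammatory monocytes, fell 8.52-fold from 236.8 ± 92.7 to 26.5 ± 8.68 FPKM (adjusted p = 0.00134), though its near copy Ly6c1 may share reads with it. Pglyrp1, a granule protein that binds bacterial peptidoglycan, fell 20.7-fold, and S1pr5, a receptor that guides monocytes out of the bone marrow, fell 17.5-fold. Gpnmb lies on mouse chromosome 6 at 49036546 to 49070929 (ENSMUSG00000029816, GENCODE vM21 on mm10), Spp1 on chromosome 5 at 104435118 to 104441050 (ENSMUSG00000029304) and Ly6c2 on chromosome 15 at 75108158 to 75111970 (ENSMUSG00000022584).

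Of 17 monocyte genes, 16 fell in treated MoMF and 1 was not called, and 17 fell when the adjustment was made over the list alone. Ifitm6 fell 12.5-fold, Sell, the adhesion receptor of circulating leukocytes, 8.43-fold, and F13a1, a coagulation factor subunit, 6.57-fold. The list was lower by camera (adjusted p = 5.93e-11), with adjusted p = 0.0904 with an estimated correlation. Ccr2, the receptor that brings monocytes into tissue (chromosome 9, 124101950 to 124113557, ENSMUSG00000049103), fell 3.19-fold from 438.9 ± 61.2 to 137.9 ± 28.7 FPKM, a call that ended without treated MoMF library 1 (log2 change -1.46, adjusted p = 0.0574). Cx3cr1 was not called (log2 change -0.74, adjusted p = 0.130), nor was the macrophage surface gene Adgre1 (0.34, adjusted p = 0.428). Among 8 neutrophil markers, some of which monocytes also express, 7 fell and none rose, with the same counts over the list alone (camera adjusted p = 1.45e-06; adjusted p = 0.139 with an estimated correlation). The calprotectin genes S100a9 and S100a8 fell 14.3-fold and 9.86-fold, and the collagenase Mmp8 fell with a log2 change of -1.93. Nfe2 fell 13.6-fold and Rasgrp4 11.1-fold. Ccr5 went the other way from Ccr2, rising 3.40-fold (log2 change 1.76 ± 0.22, adjusted p = 0.00163), and lies beside it on chromosome 9 at 124121543 to 124147699 (ENSMUSG00000079227).

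Of 15 lipid-associated macrophage genes, 14 rose in treated MoMF and none fell, and 15 rose over the list alone (camera adjusted p = 1.61e-10; adjusted p = 0.140 with an estimated correlation). The tetraspanin Cd63 rose 37.1-fold, the cysteine protease Ctsk 8.03-fold and lipoprotein lipase (Lpl) 7.37-fold. Trem2, a lipid-sensing receptor, rose 8.21-fold from 9.49 ± 0.674 to 86.4 ± 22.1 FPKM, a call that ended without treated MoMF library 1 (log2 change 2.77, adjusted p = 0.0704). In the lysosome list 14 of 22 genes rose and none fell, and 17 rose and 1 fell over the list alone (camera adjusted p = 2.10e-07; adjusted p = 0.140 with an estimated correlation). The cathepsins Ctsl and Ctsd rose 14.7-fold and 9.99-fold, and the acid lipase Lipa had a log2 change of 2.06. Of 18 scavenging, efferocytosis and complement C1q genes, 17 rose, and 17 rose over the list alone (camera adjusted p = 5.09e-11; adjusted p = 0.139 with an estimated correlation). Some of these are also Kupffer cell genes: with the Kupffer cell share of treated MoMF subtracted, 13 were higher and 1 lower, and the median change fell from 2.86 to 2.10. Mertk, a receptor for dying cells, rose 17.1-fold, C1qb 12.8-fold and the mannose receptor Mrc1 10.1-fold. Iron and heme genes moved the same way, 12 of 16 higher and 13 over the list alone (camera adjusted p = 4.97e-06; adjusted p = 0.171 with an estimated correlation), and 10 were higher and 1 lower with that share subtracted. The iron exporter Slc40a1 rose 20.3-fold, and log2 changes were 2.18 for ferritin heavy chain (Fth1) and 2.15 for heme oxygenase (Hmox1). Hamp of the iron list also rose (log2 change 4.11). It is a hepatocyte gene as well, and no hepatocyte share was subtracted.

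Inflammatory cytokine and NF-kB target genes were 12 of 15 higher and none lower, with 12 higher over the list alone (camera adjusted p = 7.35e-07; adjusted p = 0.285 with an estimated correlation). Il1a rose 51.5-fold, Il1b 11.1-fold to 1187 ± 114 FPKM and Ptgs2, the inducible cyclooxygenase, 5.88-fold, and the anti-inflammatory cytokine Il10 rose as well (log2 change 4.11). Tnf rose 3.39-fold (adjusted p = 0.0108), with a call that ended without treated MoMF library 2 (log2 change 1.56, adjusted p = 0.0741) or without untreated MoMF library 1 (1.47, adjusted p = 0.0671). Of 20 chemokines, 9 rose and 11 were not called, also over the list alone (camera adjusted p = 0.000161; adjusted p = 0.285 with an estimated correlation). The neutrophil attractant Cxcl2 rose 36.0-fold, Ccl4 10.5-fold, Ccl2 6.70-fold and Cxcl16 5.67-fold. Matrix genes were 13 of 21 higher and 3 lower, and 14 higher and 3 lower over the list alone (camera adjusted p = 0.000124; adjusted p = 0.171 with an estimated correlation), with thrombospondin 1 (Thbs1) 22.1-fold and Timp3 16.6-fold higher. NRF2 targets were 9 of 12 higher and 1 lower, and 11 higher and 1 lower over the list alone (camera adjusted p = 1.04e-05; adjusted p = 0.139 with an estimated correlation). The metallothionein Mt2 rose 15.6-fold and sulfiredoxin (Srxn1) 10.9-fold, while glutathione reductase (Gsr) fell (log2 change -1.36), a call that ended without scaling (adjusted p = 0.051). Cell cycle genes were 12 of 24 higher, and 19 over the list alone (camera adjusted p = 6.65e-06; adjusted p = 0.289 with an estimated correlation), Stmn1 5.72-fold and Mcm3 2.26-fold among them. Immediate early and dissociation stress genes were 9 of 15 higher and none lower, also over the list alone (camera adjusted p = 0.000623; adjusted p = 0.316 with an estimated correlation), Egr1 10.4-fold among them, and 7 of 12 heat shock genes outside this list were called higher. Arg1 was not called (log2 change 1.52, adjusted p = 0.0538). It is also a hepatocyte gene, so its values in all groups may include hepatocyte RNA.

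Kupffer cell genes rose in treated MoMF together with genes of other liver cells. Of 18 Kupffer cell genes, 16 rose and none fell, with 16 over the list alone (camera adjusted p = 1.82e-10; adjusted p = 0.199 with an estimated correlation). Cd5l, an apoptosis inhibitor secreted by macrophages, rose 43.2-fold, the lectin Clec4f 18.9-fold and Vsig4, a complement receptor, 16.4-fold. Clec4f reached 63.2 ± 21.6 FPKM against 1519 ± 135.1 FPKM in treated KC. Timd4 rose 2.41-fold to 2.49 ± 0.0214 FPKM, with a call that ended without treated MoMF library 1 (adjusted p = 0.0830), treated MoMF library 2 (0.0729) or untreated MoMF library 2 (0.0749). The median level of 14 Kupffer cell genes was 7.14% and 4.25% of that in treated KC in the treated MoMF libraries. Subtracting this share brings the list close to 0 and turns genes below the median by construction, and left 8 genes higher and 3 lower (adjusted p = 0.136), with Clec4f at -1.71 and Vsig4 at -1.11. Sinusoidal endothelial markers were 11 of 12 higher, with 11 over the list alone (camera adjusted p = 6.79e-11; adjusted p = 0.183 with an estimated correlation). Clec4g rose 30.5-fold to 161.2 ± 48.3 FPKM, Oit3 23.3-fold, Lyve1 18.9-fold and Gpihbp1, the capillary anchor of lipoprotein lipase, 52.2-fold. Aqp1, a water channel of vessels and bile ducts, rose 42.3-fold and the adhesion molecule Vcam1 37.3-fold. Hepatocyte markers were 14 of 18 higher and none lower, with 16 higher over the list alone (camera adjusted p = 5.35e-06; adjusted p = 0.458 with an estimated correlation), such as Tat, Ahsg and Apoc3 with log2 changes of 3.23, 4.01 and 3.78. All 6 stellate cell markers that were tested, of 12 listed, rose, also over the list alone (camera adjusted p = 0.000428; adjusted p = 0.140 with an estimated correlation), decorin (Dcn) 10.2-fold. B and plasma cell markers went the other way, 4 of 10 lower and none higher, with 6 lower over the list alone (camera adjusted p = 0.000975; adjusted p = 0.349 with an estimated correlation), and Ighm fell from 76.9 ± 1.48 to 9.71 ± 0.906 FPKM.

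By limma, 3026 of 12729 genes differed between treated and untreated MoMF at an adjusted p below 0.05, 1915 higher and 1111 lower. Without scaling the split was 2322 higher and 577 lower, and the median change of all genes moved from 0.06 to 0.33. The authors' p-values, adjusted in the same way, gave 2915 higher and 2071 lower among the genes tested here. At a change of at least 2-fold there were 1404 higher and 649 lower genes.

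Treated KC held more RNA of inflammatory, immediate early and lipid-associated genes than untreated KC, and less RNA of hepatocyte and B cell genes. Cxcl2 (chromosome 5, 90903871 to 90905938, ENSMUSG00000058427) rose 220.8-fold, from 1.27 ± 0.540 FPKM (SD, n = 2) to 502.3 ± 137.3 FPKM (SD, n = 2; log2 change 7.79 ± 0.25, SE; adjusted p = 2.31e-05). Its relative Cxcl1 rose 97.9-fold. Nr4a1, an orphan nuclear receptor induced within minutes of stimulation (chromosome 15, 101266846 to 101274792, ENSMUSG00000023034), rose 41.8-fold from 2.22 ± 0.141 to 133.9 ± 14.3 FPKM. Gpnmb rose 41.4-fold to 62.4 ± 4.56 FPKM, and the stress hormone Gdf15 44.6-fold. Serpina1e, a serine protease inhibitor made by hepatocytes (chromosome 12, 103946931 to 103958975, ENSMUSG00000072849), fell from 180.7 ± 35.5 FPKM to 0.130 ± 0.141 FPKM, 159.8-fold on the scale of log2(FPKM + 1).

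Of 15 immediate early genes, 13 rose in treated KC and none fell, also over the list alone (camera adjusted p = 1.59e-20; adjusted p = 0.139 with an estimated correlation). Egr1 rose 37.0-fold, Atf3 26.2-fold and Btg2 11.7-fold, while the heat shock members Hspa1a and Hspa1b were not called (log2 changes 0.95 and -0.01). Of 12 heat shock genes outside the list, 3 were called higher, among them Hspa8 (log2 change 1.84, adjusted p = 0.0084), a call that ended without treated KC library 2 (adjusted p = 0.0595). The other calls, of Hsph1 and Dnajb1, both ended without treated KC library 1 (0.201 and 0.108). Egr2, a transcription factor of the same family as Egr1, rose 42.7-fold. The inflammatory list was 11 of 15 higher and none lower, with 12 higher over the list alone (camera adjusted p = 1.60e-13; adjusted p = 0.171 with an estimated correlation). Il1b rose 13.5-fold from 76.3 ± 20.7 to 1024 ± 126 FPKM (chromosome 2, 129364570 to 129371139, ENSMUSG00000027398), Tnf 12.6-fold, and the NF-kB feedback genes Tnfaip3 and Nfkbiz 20.1-fold and 12.2-fold, beside a 12.8-fold rise of Il10. Chemokines were 7 of 20 higher and 1 lower, and 9 higher and 2 lower over the list alone (camera adjusted p = 7.97e-06; adjusted p = 0.233 with an estimated correlation). Ccl4 rose 22.5-fold and Ccl2 15.2-fold from 8.46 ± 4.47 to 140.3 ± 55.2 FPKM. The receptors Cxcr4 and Ccrl2 rose 36.6-fold and 29.8-fold. Ccr2, Ccr5 and Ly6c2 were not called (log2 changes -0.22, -0.58 and 0.29), nor was Cx3cr1 (adjusted p = 0.0532).

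Lipid-associated genes were 12 of 15 higher in treated KC and none lower, also over the list alone (camera adjusted p = 2.02e-12; adjusted p = 0.139 with an estimated correlation). The macrophage elastase Mmp12 rose 31.2-fold, Cd63 17.9-fold and Spp1 10.8-fold to 11.3 ± 1.87 FPKM. Trem2 (chromosome 17, 48346401 to 48354147, ENSMUSG00000023992) rose 11.9-fold from 9.81 ± 9.23 to 102.1 ± 8.98 FPKM, with a call that ended without treated KC library 1 (log2 change 3.501, adjusted p = 0.0788) or library 2 (3.67, adjusted p = 0.0681). Hilpda, a lipid droplet protein, rose 17.4-fold, the fatty acid transporter Cd36 3.63-fold and the scavenger receptor Colec12 6.56-fold. The fatty acid desaturase Scd1 fell 6.22-fold, but it is also a hepatocyte gene, and hepatocyte markers fell in treated KC too. In the lysosome list 5 of 22 genes rose, and 9 over the list alone (camera adjusted p = 5.88e-06; adjusted p = 0.140 with an estimated correlation), the proton pump subunit Atp6v0d2 14.3-fold and the galactosidase Gla 11.6-fold. Matrix genes were 10 of 21 higher and none lower, and 11 higher and 1 lower over the list alone (camera adjusted p = 3.44e-06; adjusted p = 0.140 with an estimated correlation), with Thbs1 5.37-fold and the plasminogen activator Plau 3.87-fold higher. Stellate cell markers come from the main matrix-making cells of the liver. Of 6 tested, of 12 listed, 3 were higher and none lower. Over the list alone 4 were higher (camera adjusted p = 0.000796, and 0.140 with an estimated correlation). The limma calls of Dcn and Col3a1 ended with a pseudocount of 0.1 (adjusted p = 0.107 and 0.0754). In the ER stress list 3 of 13 genes rose, and 4 over the list alone (camera adjusted p = 0.000382; adjusted p = 0.176 with an estimated correlation), with Atf4 2.85-fold higher. Camera also called cell cycle genes higher with none of 24 called singly (adjusted p = 0.00024; adjusted p = 0.350 with an estimated correlation).

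Hepatocyte markers were 9 of 18 lower in treated KC and none higher, with 10 lower over the list alone (camera adjusted p = 8.63e-09; adjusted p = 0.348 with an estimated correlation). The urinary protein gene Mup3 fell 51.8-fold, Serpina3k 36.3-fold, Serpina1c 19.6-fold and apolipoprotein B (Apob) 12.7-fold, while Tat was not called (log2 change 0.73). Mup7 was listed at 0 in both treated KC libraries. Mup and Serpina1 genes are close copies of each other, so reads may have been split between them and the split of the fall over single copies is uncertain. B and plasma cell markers were 8 of 10 lower, and 9 over the list alone (camera adjusted p = 1.05e-09; adjusted p = 0.174 with an estimated correlation), Ighm 13.01-fold and Ms4a1 6.10-fold. Erythroid and platelet markers were 1 of 7 lower and none higher, and 6 lower and 1 higher over the list alone (camera adjusted p = 0.0139; adjusted p = 0.316 with an estimated correlation), a call that ended without untreated KC library 1 (adjusted p = 0.371), with no filter (0.190), with the filter at 5 FPKM (0.0723) and with a pseudocount of 0.1 (0.0980). The MHC class II list, whose genes B cells share with macrophages, was 3 of 12 lower and 1 higher, and 7 lower and 1 higher over the list alone (camera adjusted p = 0.00125; adjusted p = 0.285 with an estimated correlation), with H2-Ob 8.19-fold lower. The Kupffer cell identity list was 4 of 18 lower and 2 higher, also over the list alone (camera adjusted p = 0.0421; adjusted p = 0.591 with an estimated correlation), a call that ended without treated KC library 1 (adjusted p = 0.152) or untreated KC library 2 (0.148), without scaling (0.0955) and with a pseudocount of 0.1 (0.153). Clec4f stood at 1519 ± 135.1 against 2123 ± 297.3 FPKM and was not called (log2 change -0.48, adjusted p = 0.494), as were Marco (-0.70), Adgre1 (-0.99) and Arg1 (-0.27). Timd4 fell 2.74-fold from 195.3 ± 33.7 to 72.0 ± 24.1 FPKM, with a call that ended without treated KC library 1 (log2 change -1.10, adjusted p = 0.108), untreated KC library 1 (-1.63, adjusted p = 0.05) or untreated KC library 2 (-1.28, adjusted p = 0.0750). Id3, a transcription factor needed for Kupffer cell development, rose 4.19-fold.

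By limma, 963 of 12729 genes differed between treated and untreated KC at an adjusted p below 0.05, 532 higher and 431 lower. Without scaling 4010 were higher and 158 lower, and the median change of all genes moved from 0.005 to 0.71. The authors' adjusted p-values gave 1389 higher and 994 lower among the genes tested here, whereas the authors' unadjusted p of at most 0.05 with a change of at least 2-fold gave 947 higher and 1421 lower over all genes they listed. The share of higher genes among those that differed was 55.2% with and 96.2% without scaling, so the balance of both directions was not settled.

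In treated livers, MoMF held more RNA of monocyte genes and KC more RNA of Kupffer cell genes. S100a4, a calcium-binding protein of migrating cells (chromosome 3, 90603771 to 90606045, ENSMUSG00000001020), stood at 314.6 ± 53.9 FPKM (SD, n = 2) in MoMF and 7.20 ± 0.108 FPKM (SD, n = 2) in KC, 38.2-fold higher in MoMF (log2 difference 5.26 ± 0.41, SE; adjusted p = 0.00108). Clec4f (chromosome 6, 83644542 to 83656187, ENSMUSG00000014542) was 24.3-fold lower in MoMF. Spp1 was 5.37-fold higher in MoMF, at 64.7 ± 6.39 against 11.3 ± 1.87 FPKM, a call that ended with a pseudocount of 0.1. Il1b, Trem2, Tnf and Arg1 were not called between treated MoMF and treated KC (log2 differences 0.22, -0.26, -0.79 and 0.18). As a list, inflammatory genes were 4 of 15 lower in MoMF and 2 higher, also over the list alone (camera adjusted p = 0.0350; adjusted p = 0.568 with an estimated correlation), a call that ended without treated KC library 2 (adjusted p = 0.206). Immediate early genes were 2 of 15 lower, and 4 over the list alone (camera adjusted p = 0.000472; adjusted p = 0.311 with an estimated correlation). Type I interferon genes were 2 of 20 lower, also over the list alone (camera adjusted p = 0.00138; adjusted p = 0.498 with an estimated correlation), a call that ended without treated KC library 2 (adjusted p = 0.0566).

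Monocyte genes were 14 of 17 higher in treated MoMF than in treated KC and none lower, and 17 higher over the list alone (camera adjusted p = 9.25e-18; adjusted p = 0.0789 with an estimated correlation). S100a6 was 32.0-fold higher, Chil3, a chitinase-like lectin of monocytes, 20.6-fold, F13a1 16.7-fold, Ly6c2 11.8-fold and Ccr2 6.35-fold. Kupffer cell genes were 17 of 18 lower and none higher, and 18 lower over the list alone (camera adjusted p = 9.43e-24; adjusted p = 0.140 with an estimated correlation). Marco was 23.3-fold, Timd4 20.4-fold, the haptoglobin receptor Cd163 19.4-fold and complement C6 17.9-fold lower. Scavenging and complement genes were 8 of 18 lower and 2 higher, and 12 lower and 2 higher over the list alone (camera adjusted p = 1.45e-06; adjusted p = 0.157 with an estimated correlation), with Colec12 8.00-fold lower. Of 12 LXR targets 4 were lower, and 6 over the list alone (camera adjusted p = 1.48e-05; adjusted p = 0.158 with an estimated correlation), Apoc1 11.8-fold and Pltp 4.05-fold. Iron genes were 3 of 16 lower, and 5 over the list alone (camera adjusted p = 0.00021; adjusted p = 0.199 with an estimated correlation), and lysosome genes 3 of 22 lower, and 8 over the list alone (camera adjusted p = 0.000983; adjusted p = 0.183 with an estimated correlation). No erythroid or platelet marker was called, but camera called their list lower (adjusted p = 0.00904; adjusted p = 0.301 with an estimated correlation).

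Lipid-associated genes were 8 of 15 higher in treated MoMF, and 10 over the list alone (camera adjusted p = 0.000161; adjusted p = 0.199 with an estimated correlation), the fatty acid carrier Fabp4 6.89-fold and Ctsk 6.37-fold. Gpnmb was 2.72-fold higher (adjusted p = 0.0136), a call that ended without either treated MoMF library (adjusted p = 0.0864 and 0.0656) or either treated KC library (0.0939 and 0.0809). MHC class II genes were 6 of 12 higher, and 8 higher and 1 lower over the list alone (camera adjusted p = 0.000513; adjusted p = 0.267 with an estimated correlation). The dendritic cell genes Cd209a and Flt3 were 18.2-fold and 4.99-fold higher, and the migration receptor Ccr7 9.30-fold. Retnlg was 18.1-fold higher, and neutrophil markers as a list were 4 of 8 higher, and 5 over the list alone (camera adjusted p = 0.00021; adjusted p = 0.140 with an estimated correlation). Thbs1 was 11.99-fold, the lactate exporter Slc16a3 5.46-fold and the cystine transporter Slc7a11 5.27-fold higher, while the growth factor Pdgfc was 5.92-fold and the cytokine Il6 4.75-fold lower. Endothelial markers were 10 of 12 higher, and 12 over the list alone (camera adjusted p = 2.66e-12; adjusted p = 0.174 with an estimated correlation), Ptprb 5.45-fold and Clec4g 5.32-fold. None of 18 hepatocyte markers was called (camera adjusted p = 0.445), and their levels varied widely within both groups, Alb from 547.7 to 148.8 FPKM in treated MoMF libraries 1 and 2 and from 443.6 to 122.7 FPKM in treated KC libraries 1 and 2. Ccr5 was 2.34-fold lower (adjusted p = 0.0167), a call that ended without treated MoMF library 2 (0.141) or treated KC library 2 (0.11). The calls of Adgre1 (2.98-fold lower) and Ccl2 (log2 difference -1.58, adjusted p = 0.0485) ended when any of the 4 treated libraries was left out, in the order of both MoMF and then both KC libraries at adjusted p = 0.0571, 0.142, 0.0664 and 0.112 for Adgre1 and 0.215, 0.215, 0.0682 and 0.254 for Ccl2, and that of Ccl2 also without untreated MoMF library 1 (0.0726) or library 2 (0.0716).

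By limma, 1120 of 12729 genes differed between treated MoMF and treated KC at an adjusted p below 0.05, 705 higher in MoMF and 415 lower. Without scaling 1232 were higher and 172 lower, with the median difference of all genes at 0.44 in place of 0.04. The authors' adjusted p-values gave 1435 higher and 1561 lower among the genes tested here and 1764 higher and 1680 lower over all genes they listed.

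In untreated livers the same identity genes separated MoMF from KC by larger folds. Clec4f stood at 2.52 ± 1.76 FPKM (SD, n = 2) in MoMF and 2123 ± 297.3 FPKM (SD, n = 2) in KC, 641.5-fold lower in MoMF (log2 difference -9.33 ± 0.38, SE). Cd5l was 615.1-fold and Vsig4 545.6-fold lower. S100a6 was 238.6-fold higher in MoMF (adjusted p = 1.50e-05), S100a4 189.8-fold and Ly6c2 122.7-fold. Timd4 (chromosome 11, 46810800 to 46844332, ENSMUSG00000055546) was 134.6-fold lower in MoMF, at 0.458 ± 0.246 against 195.3 ± 33.7 FPKM.

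All 17 monocyte genes were higher in untreated MoMF, also over the list alone (camera adjusted p = 5.84e-14; adjusted p = 0.0789 with an estimated correlation). F13a1 was 126.8-fold, Ccr2 17.4-fold, fibronectin (Fn1) 10.8-fold and Cx3cr1 8.46-fold higher, and Chil3 was listed at 0 in both untreated KC libraries. Neutrophil markers were 7 of 8 higher, also over the list alone (camera adjusted p = 7.23e-07; adjusted p = 0.139 with an estimated correlation), S100a9 133.1-fold and S100a8 71.0-fold. Immediate early genes were 12 of 15 higher, and 13 over the list alone (camera adjusted p = 1.16e-08; adjusted p = 0.174 with an estimated correlation), Nr4a1 28.4-fold. The chemokine Ccl9 was 48.2-fold and the cytokine feedback gene Socs3 8.80-fold higher, while Cxcl13, an attractant of B cells, was 138.6-fold and Il1a 16.9-fold lower. Il1b, Ccl2, Trem2 and Gpnmb were not called between untreated MoMF and untreated KC (log2 differences 0.49, -0.39, 0.28 and 0.70). Spp1 (log2 difference 1.20, adjusted p = 0.0150) lost its call without untreated MoMF library 2 (0.0654) or untreated KC library 1 (0.0615). Tnf (1.11, adjusted p = 0.0451) lost it without either treated MoMF library (0.0669 and 0.0670), either untreated MoMF library (0.0561 and 0.2) or either untreated KC library (0.166 and 0.0602). Arg1 (-1.60, adjusted p = 0.0355) lost it without either untreated MoMF library (0.129 and 0.0981) or either untreated KC library (0.0552 and 0.131).

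Kupffer cell genes were 17 of 18 lower in untreated MoMF, and 18 over the list alone (camera adjusted p = 2.95e-16; adjusted p = 0.171 with an estimated correlation). Marco was 286.3-fold, the ficolin gene Fcna 249.3-fold and the folate receptor Folr2 204.1-fold lower. Scavenging and complement genes were 14 of 18 lower and 1 higher, and 14 lower and 2 higher over the list alone (camera adjusted p = 2.42e-08; adjusted p = 0.140 with an estimated correlation), C1qb 36.9-fold and Mrc1 26.9-fold. Iron genes were 14 of 16 lower, also over the list alone (camera adjusted p = 2.10e-07; adjusted p = 0.154 with an estimated correlation), Slc40a1 154.8-fold. LXR targets were 8 of 12 lower and 1 higher, also over the list alone (camera adjusted p = 0.000508; adjusted p = 0.183 with an estimated correlation), Apoc1 96.01-fold, Scd1 21.8-fold and Nr1h3, which encodes LXR alpha, 12.9-fold. Lysosome genes were 12 of 22 lower and 2 higher, also over the list alone (camera adjusted p = 0.00027; adjusted p = 0.174 with an estimated correlation), Ctsl 12.6-fold. Cell cycle genes were 15 of 24 lower, and 19 over the list alone (camera adjusted p = 1.48e-05; adjusted p = 0.301 with an estimated correlation). Adgre1 was 7.502-fold and Ccr5 11.9-fold lower. Scd1 and Hamp of the iron list are also hepatocyte genes, so their values may include hepatocyte RNA. All 18 hepatocyte markers were lower, also over the list alone (camera adjusted p = 1.67e-10; adjusted p = 0.311 with an estimated correlation), Mup3 31.4-fold and Apob 27.2-fold. Endothelial markers were 11 of 12 lower and 1 higher, also over the list alone (camera adjusted p = 2.40e-06; adjusted p = 0.285 with an estimated correlation), Stab2 11.8-fold lower and Flt1 higher (log2 difference 1.44), a call that ended without untreated MoMF library 2 (adjusted p = 0.0508). All 7 erythroid and platelet markers that were tested, of 12 listed, were lower, also over the list alone (camera adjusted p = 0.00194; adjusted p = 0.265 with an estimated correlation). B and plasma cell markers were 7 of 10 lower and 1 higher, also over the list alone (camera adjusted p = 0.0391; adjusted p = 0.527 with an estimated correlation). This camera call ended with the filter at 5 FPKM (adjusted p = 0.343) and with a pseudocount of 0.1 (0.098). It also ended without untreated MoMF library 2 or either untreated KC library.

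By limma, 4099 of 12729 genes differed between untreated MoMF and untreated KC at an adjusted p below 0.05, 1831 higher in MoMF and 2268 lower. Without scaling 6472 were higher and 880 lower, with the median difference of all genes at 0.84 in place of -0.01. The authors' adjusted p-values gave 2290 higher and 2791 lower among the genes tested here.

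The effects of treatment on both populations shared part of their genes. Across all genes they had a Spearman correlation of 0.232 and a Pearson correlation of 0.254. Both effects were upward for 341 called genes, against 80.04 expected if the calls were unrelated, and downward for 90, against 37.6 expected. Gpnmb, Spp1, Il1b, Cxcl2, Ccl2 and Cd63 were among the genes that rose in both, and no difference between the populations was called for Gpnmb (interaction log2 0.75, adjusted p = 0.225), Spp1 (1.22, adjusted p = 0.0931), Il1b (-0.27, adjusted p = 0.684) and Ccl2 (-1.18, adjusted p = 0.222). Equal effects are not shown by this, since 5% of 2-fold interactions were recovered in the self-test. Cxcl2 rose more in KC (interaction log2 -2.62). Opposite calls were found for 83 genes, against 111 expected. The effect differed between the populations for 1653 genes, 1091 with a higher and 562 with a lower effect in MoMF, and without scaling for 641 and 593.

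**Figure D1:**
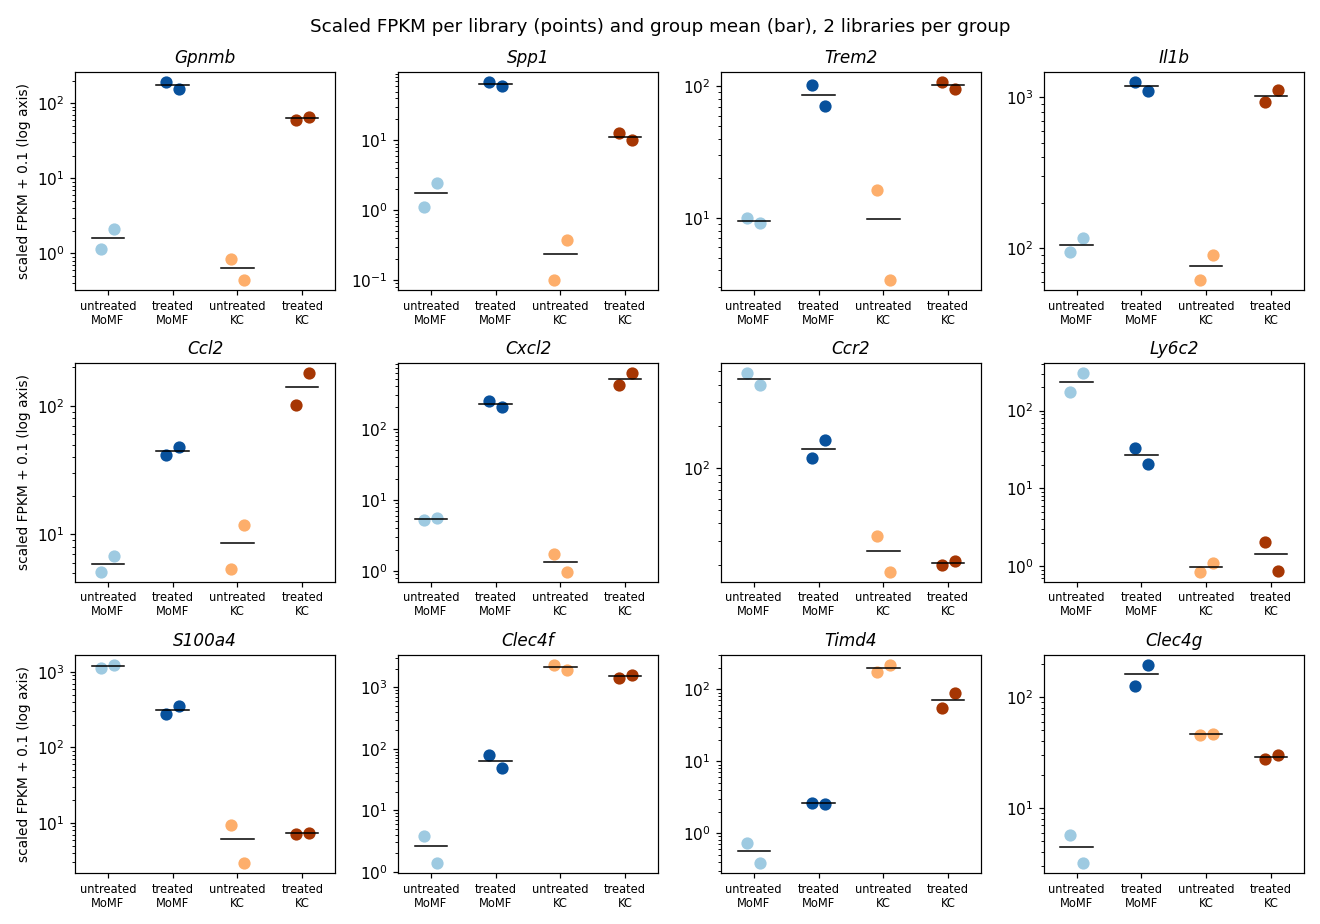
Scaled FPKM + 0.1 (log axis) of 12 genes in the 8 libraries; points are libraries and bars are group means. Gpnmb rose 69.7-fold in MoMF and 41.4-fold in KC with treatment, while Clec4f and Timd4 stayed highest in KC.

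**Figure D2:**
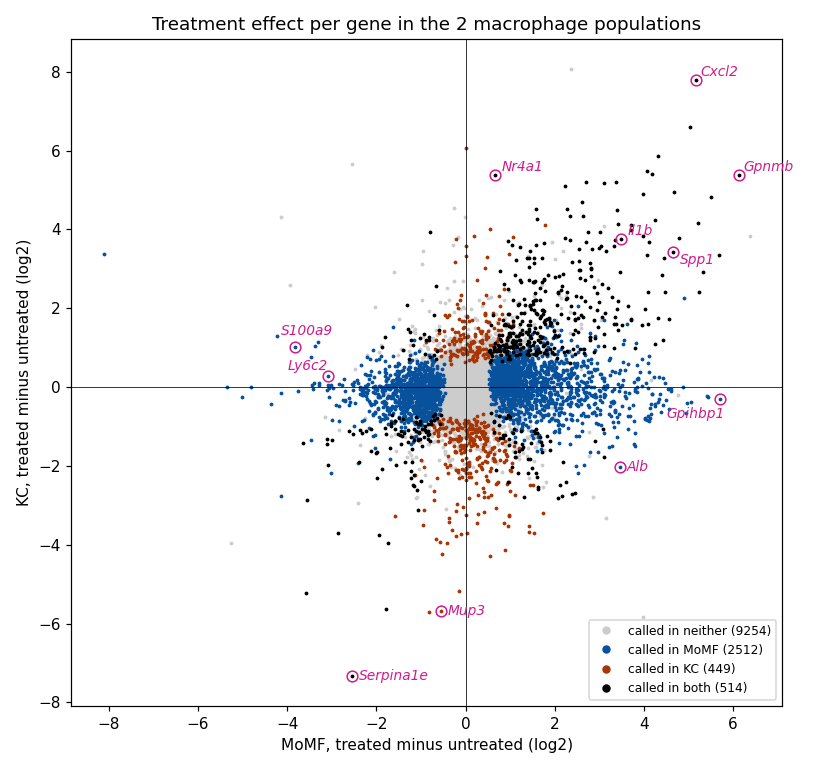
Log2 change with treatment in MoMF (horizontal) and in KC (vertical); each point is a gene, coloured by the population in which it was called. 514 genes were called in both populations, 2512 in MoMF alone and 449 in KC alone.

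**Figure D3:**
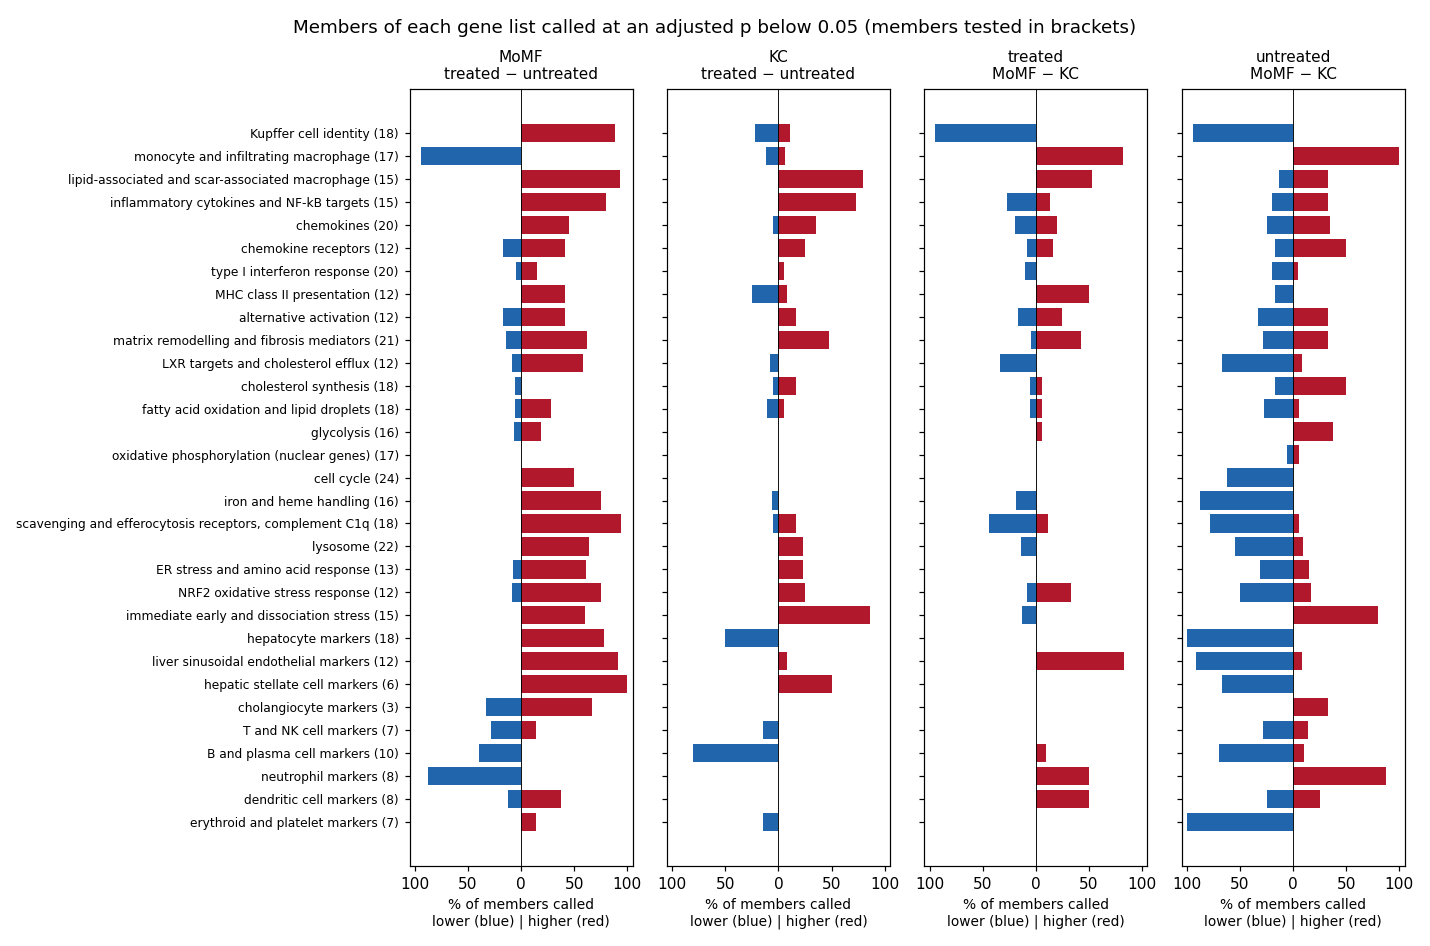
Percent of the members of each gene list called higher (red) or lower (blue) in the 4 comparisons. Kupffer cell genes were 16 of 18 higher in treated MoMF, and immediate early genes 13 of 15 higher in treated KC.

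**Figure D4:**
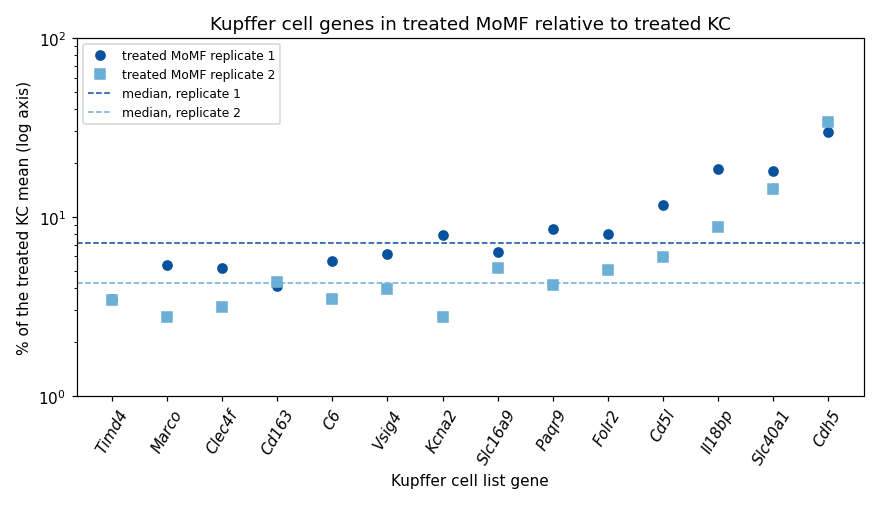
Level of 14 Kupffer cell genes in both treated MoMF libraries as percent of the treated KC mean; points are genes and dashed lines are medians. The medians were 7.14% and 4.25%. Cdh5 was highest at a mean of 31.8%, followed by Slc40a1 at 16.2% and Il18bp at 13.6%.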

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

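The interaction between treatment and population was planned, and among the tests of what lay behind it those of cell carry-over, of scaling and of a common hepatocyte factor were chosen after the results were seen. In all, 1653 genes had a treatment effect that differed between MoMF and KC. The largest positive interactions, the effect in MoMF minus that in KC, were those of Gpihbp1 (log2 6.003), Cd5l (5.69), Aqp1 (5.63), Clec4g (5.59), Alb (5.49) and Igfbp7 (5.44). The most negative were S100a9 (-4.86), Nr4a1 (-4.73), S100a8 (-4.46), Tppp3 (-4.22), S1pr5 (-3.99) and Pglyrp1 (-3.95). Among marker genes, interactions were found for Clec4f (4.72), Marco (3.62), Timd4 (2.73), Ccr5 (2.34), Tnf (-1.90), Cx3cr1 (-1.99) and Ly6c2 (-3.38). Adjusted p for Alb rose from 0.0182 to between 0.0524 and 0.0607 without treated MoMF library 1, either untreated MoMF library or untreated KC library 1. For Cx3cr1 it rose from 0.0258 to between 0.0665 and 0.0918 when any treated library or any untreated MoMF library was left out. For Tnf it rose from 0.0452 to between 0.0585 and 0.154 when any library other than treated KC library 1 was left out. The call of Ccr5 ended without scaling.

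Among lists called by camera, positive median interactions were those of hepatocyte markers (4.83), sinusoidal endothelial markers (4.59), Kupffer cell identity (2.93), scavenging and complement (2.80), NRF2 targets (1.57), iron and heme (1.53), MHC class II (1.42), erythroid and platelet markers (1.32), B and plasma cell markers (1.05), LXR targets (0.90), cell cycle (0.60) and lysosome (0.43). The called lists with negative medians were immediate early genes (-2.33), neutrophil markers (-1.82), monocyte genes (-1.75) and inflammatory genes (-0.27). With an estimated correlation none of these lists was called, and the lowest adjusted p of any list in any comparison was 0.0789. The calls of the LXR, cell cycle, lysosome, erythroid, B cell and inflammatory lists also ended without scaling, and those of the LXR, cell cycle, lysosome, erythroid and inflammatory lists without at least 1 of the libraries. For list LXR targets and cholesterol efflux, interaction, adjusted p was 0.0643 without treated MoMF library 1, 0.104 without untreated MoMF library 2 and 0.0572 without treated KC library 1. For list lysosome, interaction, it was 0.0644 without treated MoMF library 1. For list cell cycle, interaction, it was 0.282 without treated MoMF library 1, 0.130 without untreated MoMF library 1, 0.201 without treated KC library 2 and 0.0543 without untreated KC library 2. For list inflammatory cytokines and NF-kB targets, interaction, it was 0.145 without untreated MoMF library 2, 0.0613 without treated KC library 2 and 0.150 without untreated KC library 1. For list erythroid and platelet markers, interaction, it was 0.0755 without treated MoMF library 1, 0.261 without untreated MoMF library 1, 0.0640 and 0.0589 without either treated KC library and 0.362 without untreated KC library 1.

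Kupffer cell and endothelial genes may have risen in treated MoMF because cells or RNA of both kinds were carried over in the sort, in line with 78.6% of 14 Kupffer cell genes lying within 2-fold of a median ratio of 5.54% to treated KC. Kupffer cells as the only source would place Cdh5 near that ratio, but it stood 5.74-fold above it in FPKM. Slc40a1 (16.2%) and Il18bp (13.6%) also lay more than 2-fold above that ratio. A moderated t test on the log2 scale did not call them (adjusted p = 0.0915 for both). On the log2 scale Cdh5 lay 2.115 above the median difference (moderated t test, adjusted p = 0.00143). The same test also called Kcna2 (adjusted p = 0.00602) and Paqr9 (0.00792), genes of low expression at 5.33% and 6.37% of treated KC. Its p-values thus depend on the scale, and Kupffer cells as the only source of Cdh5 were argued against but not excluded. Endothelial cells or their RNA would give endothelial genes a common ratio, and 83.3% of 12 genes lay within 2-fold of a ratio of 5.17. Endothelial RNA that came along with Kupffer cells alone would leave the endothelial list lower in treated MoMF than in treated KC. It was higher instead (median log2 difference 2.0003, SE 0.159 across the 12 genes and not across libraries), which argues against this source. The genes moved together (estimated correlation 0.535), so this SE understates the spread. With that correlation camera did not call the list (adjusted p = 0.174). MoMF that turn on Kupffer cell genes could give part of the same rise, and single-cell RNA of the sorted MoMF would show whether Clec4f came from few cells at the Kupffer cell level or from many at a low level.

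Immediate early genes may have risen in treated KC through handling stress that differed between the livers, which stayed open. Heat shock genes had a median change of 0.79 (SE 0.202 across 12 genes and not across libraries) against 3.54 for the immediate early list. Of these 12 genes 3 were called higher, each losing its call without some KC library. In MoMF the median changes were 0.87 for heat shock genes and 0.95 for the immediate early list, so both rose there too. The median rise of the list was between 3.19 and 4.42 under both scalings, 2 other settings and a limit to genes of higher expression. The choice of scaling was too small a factor to give this rise, as dropping it moved the median of all genes in KC only from 0.005 to 0.71. The lower depth of the untreated KC libraries went with the label, was not equalised and was not tested as a source. Fos and Egr1 measured in KC fixed before dissociation would tell handling from treatment.

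Hepatocyte genes may have fallen in treated KC in part because a smaller amount of hepatocyte RNA entered the sort, a part that stayed open with 58% of 50 hepatocyte genes within 2-fold of their median change of -1.78, and 50% when plain FPKM ratios were used. A further count, chosen after these 2 measures had been seen, argued against a smaller amount of unchanged composition as the only source. It cannot exclude that source, as most genes that fell further in it were Mup and Serpina1 genes, whose split over copies is uncertain. In this count 17 of the 50 genes differed from the median change. Among these, 10 fell further, such as Serpina1e, Mup3 and Apob, and 7 lay above the median, from Apoa4, itself called higher in treated KC (log2 change 3.79, adjusted p = 0.0192, but 0.105 without treated KC library 1 and 0.0689 and 0.0691 without either untreated KC library), to Pck1 and Hamp, which were not called. Hepatocyte RNA whose own composition differed between treated and untreated livers was in line with a Spearman correlation of 0.690 between the effects in MoMF and KC over these genes (Pearson 0.804). RNA of the livers before sorting would show whether Mup and Serpina1 genes fell there too.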

How the results depend on the processing

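No scaling, the authors' deposited p-values and the subtraction of a Kupffer cell share were chosen after the results were seen. The other alternatives were planned. With the authors' p-values the number of genes that differed grew from 3026 to 4986 in MoMF, from 963 to 2383 in KC and from 1120 to 2996 between treated MoMF and KC. Without scaling it grew to 4168 in KC and from 4099 to 7352 between untreated MoMF and KC. With only the 4 libraries of the groups compared it was 3059 in MoMF, 510 in KC, 1402 between treated and 2776 between untreated populations. With an estimated correlation between genes 0 of 87 called list tests stayed called. Lists with a negative estimate lost their call as well, such as monocyte genes (-0.0217) and NRF2 targets (-0.0273) in MoMF. For these the loss did not come from correlation between their genes, and its source was not tested. With fry, a self-contained test that does not set a list against other genes, 97 were called. Of the 87, 75 stayed called with fry, with direction not compared. Leaving out 1 library gave 1418 to 3412 genes in MoMF, 341 to 795 in KC, 254 to 1252 between treated and 2712 to 3715 between untreated populations, and 809 to 1510 for the interaction, while the correlation of the treatment effects ranged from 0.206 to 0.247 and the called lists from 80 to 90. Calls of MoMF fell most without either treated MoMF library (1418 and 1571) or either untreated MoMF library (1666 and 1929), and calls of KC without either treated KC library (360 and 341) or untreated KC library 1 (519). Between treated populations they fell to 539 and 254 without a treated MoMF and to 348 and 294 without a treated KC library, and between untreated populations to 2712 without untreated MoMF library 1. The interaction fell to 809 and 910 without a treated MoMF, to 961 and 1028 without an untreated MoMF and to 864 and 814 without a treated KC library. When a library was left out, the lone library of its group was assumed to vary like the other groups. Subtracting a Kupffer cell share reversed the MoMF changes of Clec4f (-1.71), Timd4 (-0.53), Marco (-0.44) and Vsig4 (-1.11) and the interactions of Clec4f (-1.23), Vsig4 (-0.32) and Cd163 (-0.65), by construction for genes below the share, which is their own median. No scaling reversed Acox1 in KC (0.18) and Cd80 (0.30), Sdf2l1 (0.31) and Clec9a (0.072) between untreated populations. Of 484 called results of named genes, 481 stayed called with median-ratio scaling, 451 and 461 with pseudocounts of 0.1 and 5, and 397 without scaling. The cause of these shifts was not tested.

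With the replicate number as a block, as a check of pairing, 2913, 948, 1017, 4050 and 1589 genes differed in MoMF, KC, treated, untreated and the interaction, the correlation of the treatment effects was 0.232 and 89 lists were called, without the erythroid and platelet list in the interaction (adjusted p = 0.0547). Residual correlations between libraries of the same replicate number were -0.0375, 0.153, -0.0168, 0.103, 0.0633 and -0.0185 over the pairs of groups. The highest, 0.153, joined treated MoMF and treated KC, where hepatocyte genes such as Alb and Ahsg were higher in library 1 of both groups. These libraries may have shared a liver or preparation, a hint from the data and not the labels. The hint is weak, since the next highest, 0.103, joined treated MoMF and untreated KC, which differ in label.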

Other observations

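The patrolling monocyte genes were chosen before their result was seen, and none of the values in this part was picked by a test chosen afterwards. With treatment in MoMF, none of 17 oxidative phosphorylation genes was called (camera adjusted p = 0.678), and 1 of 18 cholesterol synthesis genes fell (camera adjusted p = 0.439). Of 18 genes of fatty acid oxidation and lipid droplets, 5 rose and 1 fell (camera adjusted p = 0.155), with Hilpda 13.1-fold higher, and of 16 glycolysis genes 3 rose and 1 fell (camera adjusted p = 0.983). Type I interferon genes were 3 higher and 1 lower (camera adjusted p = 0.488), and T and NK cell markers 1 higher and 2 lower. Genes of alternative activation parted, with Mrc1 10.1-fold higher and Retnla 10.6-fold lower in treated MoMF (camera adjusted p = 0.571). In treated KC, Cd93 rose (log2 change 2.03) and Clec7a, a receptor for fungal glucans, rose (1.61).

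Genes of patrolling monocytes were lower in treated than in untreated MoMF. Spn, a sialoglycoprotein of leukocytes, fell from 99.7 to 9.25 FPKM (log2 change -3.29), the angiotensin-converting enzyme Ace from 109.4 to 14.6 FPKM (-2.84) and Cd300e from 46.3 to 4.46 FPKM (-3.11). The transcription factor Klf2 went the other way, from 26.6 to 45.9 FPKM (0.76), a call that ended without either treated MoMF library (adjusted p = 0.118 and 0.0642) or either untreated MoMF library (0.0878 and 0.0701), and Gngt2 was not called (-0.41).

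The untreated MoMF sort may have held patrolling monocytes, in line with 10 of 12 of their genes being lower in treated MoMF (median log2 change -1.83). Not all of these genes set the cells apart, since 5 of the 12 were as high or higher in untreated KC than in untreated MoMF, such as Cd300e at 70.1 FPKM and Adgre4 at 199.3 FPKM, and 3 were also called lower in treated KC. The same sort had higher S1pr5, which monocytes of that kind also use. Sorting untreated MoMF by Ly6C and counting the Ly6C-low cells would decide between a loss of these cells and a fall of the genes within each cell.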
